A study of Mus musculus with 2 samples.

How the data were processed

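DNase-seq libraries from the left cerebral cortex of 2 male mice aged 10 days were compared as biological replicates 1 and 2 of 1 group. The labels number the males apart and give both the same donor identifier. Each has 1 technical replicate per the labels. The coordinates are on mm10, per the labels and the deposited records. For each library the deposited material held a shorter and a longer peak list, a list of base runs with an FDR, and a list of footprints. Per the deposited records, each was made from the filtered alignments of that library alone, so peaks were called per sample and not pooled. The aligner, the peak and footprint callers and their versions are not given in the sources used here. Reads carrying CAST variants align to a reference of another strain, which lacks them, and allele-specific values were not analysed here.

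The peak lists give a deposited signal per peak, the height of the peak, on a scale whose normalisation is not stated. The signal is the authors' own value and was used to describe, rank and filter peaks and to correlate pairs. Every signal value was a whole multiple of 1 step per library within a tolerance of 0.1 of a step (100% of the values of the longer list in both libraries). The step was 0.0040 in replicate 1 and 0.00498 in replicate 2, a ratio of 1.25. If 1 step is 1 counted cut, the median peak of the shorter list rested on 228 counts in replicate 1 and 191 in replicate 2. The deposited FDR file holds q-values per run of bases and lists only those at 0.05 or below. The smallest q-value within a peak was at most 0.001 in the shorter and 0.05 in the longer list of each library. The deposited footprint score was 0.01 in every row and ranked nothing, so only positions were used.

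The shorter list was taken as the main peak list after the structure of the files was seen and before any overlap or gene list was computed. The FDR runs were merged into regions, 326847 in replicate 1 and 249607 in replicate 2. Genes, transcripts and exons came from GENCODE vM21 and sequence from the GRCm38.p6 reference, the same build as mm10. Of 21911 protein-coding genes, 21826 had a coding transcript and entered the TSS tests. Chromosomes other than the numbered ones, X and Y were not used. Peaks were classed as TSS-proximal if they overlapped 500 bp on either side of a protein-coding TSS and otherwise by the feature at their centre. Distal peaks were those more than 1 kb from any protein-coding TSS.

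Peak overlap needed at least 1 bp and was set beside 100 random placements on the same chromosomes, and footprint overlap beside 100 placements inside the same peak. For the alternative of 50% reciprocal overlap of peaks, the placements were counted at 1 bp, which is an upper bound of chance. Only footprints lying wholly within a peak can be placed this way, 54.3% of those in replicate 1 and 57.3% in replicate 2. Gene lists were tested for TSS peaks in both libraries by two-sided Fisher's exact tests against all other genes. For distal peaks they were tested by two-sided permutation against 10000 random lists matched on the decile of window length. Motifs were searched on both strands in footprints extended by 5 bp on each side, and in as many segments of the same width placed in the same peak outside footprints. A footprint for which no such segment was found was left out (11690 in replicate 1 and 5235 in replicate 2). A motif was called where both libraries passed 0.05 in the same direction. A motif with 0 background counts was set against a floor of 3 counts. All p-values within a family were adjusted by the Benjamini-Hochberg method. Lists and motifs compare genes or sites within these 2 libraries, and the p-values do not measure the spread between animals.

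The 18 gene lists, the 26 motif consensus sequences, the tests, most alternatives and the rule for named items were fixed before the data were examined. The rule took, per list, the 2 genes with the highest mean rank of TSS signal among those with a peak in both libraries and the alphabetically leading 2 with none in either. It also took the 10 shared peaks and 5 distal shared peaks with the highest mean signal rank, the 10 genes with the most shared distal peaks, the 3 library-only peaks of highest signal per library, and every motif. Items on chromosome 18 stayed in the tests but are not named. Some other items that the rule takes are not reported here, and they stayed in the counts and tests. All listed symbols matched the annotation. Pdgfra stands in the oligodendrocyte and meningeal lists and Ttr in the meningeal and liver lists.

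For the closing comparison of the libraries, TSS signal was turned into a percentile among equal numbers of peaks per library, with absent peaks at 0. The median difference of a list was placed among 10000 random lists of the same size matched on mean percentile, and also on promoter GC content. Promoter GC and CpG content were those within 500 bp of the 5' end of a gene. Its TSS peak could lie at another TSS. The range over the 5 non-neuronal lists of the median difference, standardised by its matched lists, was placed among sets of 5 matched lists. Earlier forms of this comparison were the lowest glial percentile, a permutation of genes between the sets, and the difference between the merged vascular and meningeal and the merged glial lists. They excluded a lower neuronal share, and were set aside because they rested on 1 list, took genes as replicates, or picked the lists after their percentiles were seen. Absence of a peak in replicate 2 was compared with 10000 lists matched on the decile of replicate 1 signal. Motifs in the central 200 bp of library-only distal peaks were compared by a Mantel-Haenszel odds ratio over deciles of GC content. These steps were added after the overlap and the list counts were seen, and those of the 5 lists and of absence last, after the list percentiles.

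Alternatives were a 50% reciprocal overlap, the higher-signal part of each list, equal numbers of peaks, the merged FDR regions, other TSS windows, body margins, distal distances, padding and backgrounds, matching on promoter CpG content, chromosome length without unknown bases, and each replicate alone. The longer peak list, TSS-proximal pairs alone and every footprint were added after the files were seen. A result counted as turned round only where it was called in at least 1 of the settings compared.

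The statistics were tested on simulated data. For 20000 simulated peaks with 49.6% planted as shared, 49.7% were recovered. In simulations with 20000 genes, 98.8% of lists of 16 with a changed TSS share were called and 0.571% of unchanged ones. For distal counts the shares were 95% and 1.43%. The planted changes, a fall in the TSS share and a rise in distal counts, were about as large as the strongest results here. Smaller differences were not simulated, so a list that was not called may still differ. Of 500 planted CREB/ATF sites in 50000 simulated footprints, 499 were found beyond background, and 0 of 25 other motifs were called. A planted odds ratio of 3 was recovered as 3.10. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.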

Results

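Accessible chromatin was mapped by DNase-seq, in which the enzyme DNase I cuts DNA in open chromatin and the cut sites are sequenced, in the left cerebral cortex of male B6CASTF1/J mice aged 10 days. These mice are first-generation hybrids of a laboratory strain and the wild-derived CAST strain. The series held 1 group of 2 libraries, biological replicates 1 and 2, and the labels name a different male for each, under 1 shared donor identifier. With 1 group, the comparisons were between the 2 replicates, between gene groups within the libraries, and between motifs in protected sites. Replicate 1 had 113325 peaks covering 21.0 Mb and replicate 2 had 91754 peaks covering 16.9 Mb, with a median width of 180 bp in both. Footprints, short stretches protected from cutting inside accessible DNA, numbered 521809 in replicate 1 and 416814 in replicate 2. Total read numbers are not given in the sources used here, so the lists themselves were the measure of depth. Replicate 1 had 1.24 times as many peaks and 1.25 times as many footprints as replicate 2.

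The most accessible sites of the cortex shared by the 2 libraries lay mostly at promoters. Among the 10 shared peaks with the highest mean rank were those at the transcription start sites (TSSs) of Hjurp, a centromere histone chaperone (chromosome 1, 88277521 to 88277740, mm10), Snrnp70, a splicing component (chromosome 7, 45395701 to 45395980), and Fzr1, an activator of the anaphase-promoting complex (chromosome 10, 81378541 to 81378780). The signal at Hjurp was 52.4 in replicate 1 and 34.1 in replicate 2. The peaks at Bahcc1, Dynlt1b, Dnpep and Mxd1 also belonged to this group. Of these 10 peaks, 3 lay more than 1 kb from any protein-coding TSS. They were 10.3 kb from the TSS of Cox14, in an untranslated exon, 11.5 kb from that of Gm21887, inside Mid1 near the end of chromosome X, and 5.60 kb from that of Ubqln1, in an untranslated exon. Several footprints of the peak near Gm21887 hold the same run of bases. Whether this repeated sequence affects its signal was not tested. A peak 1.31 kb from the Bahcc1 TSS and one 35.5 kb from that of Pak3, a kinase gene on chromosome X (143482981 to 143483140), both intergenic, completed the 5 highest distal peaks.

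Of the peaks of replicate 1, 48.7% overlapped a peak of replicate 2 by at least 1 bp, and 59.9% of the peaks of replicate 2 overlapped one of replicate 1. Random placements of the other library's peaks on the same chromosomes gave 1.37% and 1.69% on average (permutation p = 0.0099 each, the smallest value 100 placements can give). With the larger library reduced to the number of peaks of the smaller by signal, the shares were 58.4% and 58.2%. The shared regions numbered 53920, and 62.2% of them lay more than 1 kb from a protein-coding TSS.

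Whether a peak of replicate 2 was shared went with its base composition, a comparison chosen after the overlap was seen. In the lowest GC decile of its peaks 26.1% had a partner in replicate 1, and in the highest decile 95%. In replicate 1 the share was 49% in the lowest decile, 41.5% at its lowest and 71.2% in the highest decile. Among its distal peaks it lay between 37.2% and 49.1%, and among those of replicate 2 between 25.5% and 92.4%. Peaks of replicate 2 alone had a median GC content of 49.7%, against 56.8% for its shared peaks, while in replicate 1 the medians were 55.6% and 57.5%.

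**Figure D1:**
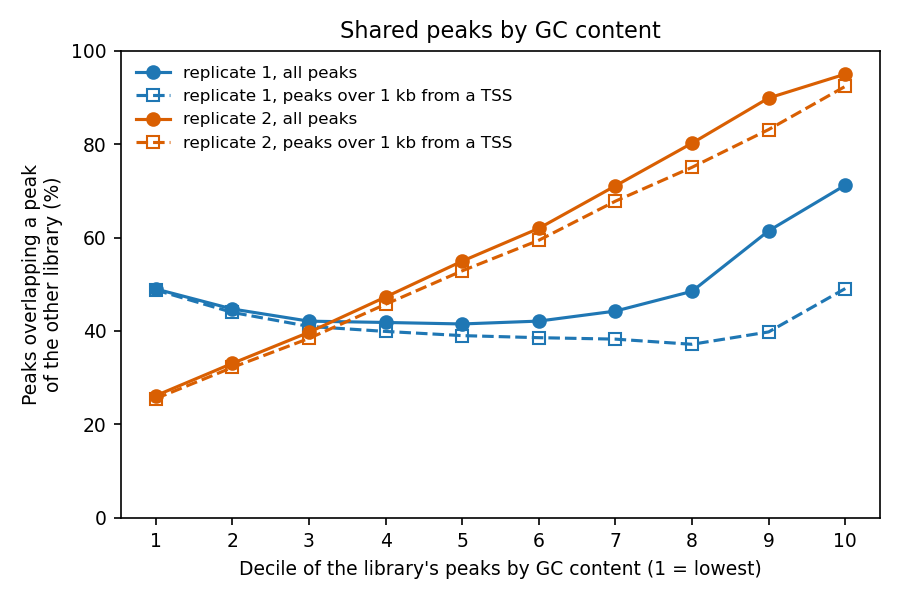
Share of each library's peaks that overlapped a peak of the other library (vertical axis, %) by decile of GC content of its peaks (horizontal axis, from lowest to highest). Filled circles show all peaks and open squares peaks more than 1 kb from a TSS. The share in replicate 2 went from 26.1% to 95%, and that in replicate 1 stayed between 41.5% and 71.2%, each over all peaks. Over distal peaks replicate 1 stayed between 37.2% and 49.1%.

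Many library-only peaks had weaker support in the other library. Of the 58168 peaks of replicate 1 alone, 31.1% (95% exact binomial interval 30.7 to 31.4) overlapped at least 1 base of replicate 2 at a false discovery rate (FDR) of 0.05 or below. Of the 36767 peaks of replicate 2 alone, 45.7% (45.2 to 46.2) overlapped such a base of replicate 1. No position at this level was found in the other library for 35.4% of all replicate 1 peaks and 21.7% of all replicate 2 peaks. The intervals cover counting error only. Library-only peaks were weaker, with a median signal of 0.568 against 1.61 for shared peaks in replicate 1, and 0.657 against 1.33 in replicate 2. The highest library-only peaks lay near Napa, Zbtb20 and G3bp1 in replicate 1 (signal 17.6, 17.4 and 16.6) and near Fdxr, Zfp446 and Atl3 in replicate 2 (8.76, 8.27 and 8.14). All 6 overlapped the other library at an FDR of 0.05 or below, and none was in its longer peak list.

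The order of sites by signal was more alike in the 2 animals at promoters than at distal sites. Across 54280 pairs of overlapping peaks, the Spearman correlation of signal was 0.724 and the Pearson correlation of log2 signal 0.806. Over the 18049 TSS-proximal pairs the Spearman correlation was 0.897, and over the 33719 distal pairs it was 0.561. These correlations are across peaks, which are not independent replicates, so no p-value was given. Signal differed by less than 2-fold in 74.1% of pairs. The level shifted more at promoters, with a median log2 difference of replicate 1 from replicate 2 of 0.649 for TSS-proximal and 0.105 for distal pairs. Allowing for the median shift between libraries, 21.9% of pairs differed by no more than the counting error that holds if 1 step of the signal is 1 counted cut.

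Promoters made up a far larger part of the shared peaks than of the library-only peaks. TSS-proximal peaks, those overlapping the 500 bp on either side of a protein-coding TSS, were 22.3% of the peaks in replicate 1 and 22.1% in replicate 2, against 1.64% and 1.61% of randomly placed intervals of the same widths. They were 33.4% of shared and 11.7% of library-only peaks in replicate 1 (odds ratio 3.79, 95% interval 3.67 to 3.91). In replicate 2 they were 33.2% and 5.61% (odds ratio 8.37, 95% interval 7.98 to 8.78). With only the higher-signal part of each list the odds ratios were 2.19 and 11.9, and with 200 bp on either side of the TSS 4.99 and 13.3. Both two-sided Fisher's exact tests gave p-values below the smallest number the software represents. Coding exons held 7.23% of the peaks of replicate 1 alone and 2.30% of those of replicate 2 alone. Intergenic positions held 30.9% and 41.1% of them.

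Promoters of neurons, dividing cells and housekeeping genes were accessible in both animals. A TSS peak was present in both libraries for 15 of 16 pan-neuronal genes, 18 of 20 genes of cortical glutamatergic neurons, 17 of 17 activity-regulated genes, 14 of 14 cell proliferation genes and 16 of 16 housekeeping genes. Among all other protein-coding genes the share was 59.3% to 59.4%. Uchl1, a ubiquitin hydrolase abundant in neurons, had a TSS signal of 4.92 in replicate 1 and 7.28 in replicate 2, and Tubb3, the neuronal tubulin, 4.20 and 7.08. In the glutamatergic list the highest were Lhx2, a homeodomain factor of the developing cortex (4.68 and 4.74), and Gria2, an AMPA receptor subunit (3.86 and 5.60). Among activity-regulated genes outside chromosome 18, Jun (14.5 and 15.4) and Junb (11.04 and 8.04), subunits of the AP-1 factor, ranked highest. The proliferation list was led by the replication helicase gene Mcm5 (14.7 and 13.8) and the cyclin gene Ccna2 (15 and 9.71), the housekeeping list by Ywhaz (15.8 and 13.5) and the chaperone gene Hsp90ab1 (19.9 and 11.01).

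These 5 lists were above other genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 18 lists, with adjusted p = 0.0077 for both neuronal lists, 0.000634, 0.00313 and 0.00101 for the others in the order given. Against random lists matched on promoter CpG content, the activity-regulated (permutation adjusted p = 0.141) and proliferation lists (0.662) were no longer called. Both lists were already complete, against 85.6% and 90.7% on average in their matched lists. No higher share was possible, so this test could not have called them and does not tell whether CpG content accounts for them. With only the higher-signal part of each peak list, the pan-neuronal (Fisher's exact adjusted p = 0.0533) and glutamatergic (0.0857) lists also missed the threshold.

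Promoters specific to other organs and to posterior body identity were mostly closed. A TSS peak in both libraries was found for 0 of 21 Hox genes, which pattern the trunk and hindbrain, 1 of 16 liver genes, 1 of 15 striated muscle genes, 1 of 14 lymphocyte genes, 1 of 14 germ cell genes, 2 of 12 erythroid genes and 2 of 12 genes of meningeal fibroblasts and choroid plexus. The meningeal genes were an exception in replicate 1, where 8 of 12 had a TSS peak. The exact 95% upper limit for the Hox share was 16.1%, for counting error in the shorter list alone. In replicate 1 alone 5 of 21 Hox genes had a TSS peak, with an upper limit of 47.2% (Fisher's exact adjusted p = 0.00049, still below other genes). With the longer list 4 of 21 Hox genes had a TSS peak in both (Fisher's exact adjusted p = 0.000191, still below other genes). No TSS peak was found in either library at Hoxa13 and Hoxa2, at the liver genes Afp and Ahsg, at the muscle actin genes Acta1 and Actc1, at the B-cell gene Blk, at the sperm genes Acrv1 and Prm1, or at the erythroid genes Alas2 and Epb42. Exceptions with a peak in both were Apoh (1.12 in replicate 1 and 0.712 in replicate 2), Mylpf (8.90 and 9.14), Foxp3 (1.64 and 0.588), Dazl (6.85 and 2.14) and Epor (3.63 and 1.34). A peak at any annotated coding TSS of a gene counted. Whether these peaks mark the promoter used in the other organ, or that of a neighbouring gene, was not tested.

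All 7 of these lists were below other genes, with Fisher's exact adjusted p = 1.08e-07 for Hox, 0.00012 for liver, 0.000185 for muscle, 0.000257 for lymphocyte and for germ cell, and 0.0077 for erythroid and meningeal genes. Matched on promoter CpG content, the liver (permutation adjusted p = 0.085), lymphocyte (0.116) and erythroid (0.97) lists were no longer called, and the striatal, thalamic and hindbrain list (8 of 18) became lower (0.0024). With FDR 0.05 regions in place of peaks the meningeal list was 5 of 12 and no longer called (Fisher's exact adjusted p = 0.164), and in replicate 1 alone it was 8 of 12 (adjusted p = 1).

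For the non-neuronal cell types of the cortex, the share with a TSS peak in both libraries did not differ from other genes. It was 12 of 16 for astrocytes (Fisher's exact adjusted p = 0.347), 8 of 15 for the oligodendrocyte lineage (0.794), 6 of 15 for microglia (0.24) and 8 of 16 for vascular cells (0.483). With only the higher-signal part of each peak list the microglial (3 of 15, Fisher's exact adjusted p = 0.0229) and vascular (2 of 16, 0.00303) lists became lower than other genes. For GABAergic interneurons it was 15 of 20 (0.24), and for striatal, thalamic and hindbrain genes 8 of 18 (0.279). The striatal, thalamic and hindbrain list also became lower with the higher-signal part (4 of 18, Fisher's exact adjusted p = 0.013), and the interneuron list became higher with the longer peak list (19 of 20, 0.0034) and with FDR 0.05 regions (0.00595). The highest astrocyte promoters were those of Glul, glutamine synthetase (13.5 in replicate 1 and 9.04 in replicate 2), and the transcription factor Nfia (14.2 and 7.15). Olig1 (2.28 and 2.71) and Olig2 (2.05 and 2.37), factors of the oligodendrocyte lineage, had a peak in both, while the myelin genes Mag and Mobp had none in either. Among microglial genes Irf8 (5.21 and 2.46) had a peak in both and Aif1 and Itgam none in either. Maf (3.47 and 2.68) led the interneuron list, in which Lhx6 and Sst had no peak. In the striatal, thalamic and hindbrain list Tcf7l2 (4.03 and 1.65) had a peak in both, and Pax2 and Pax7 had none.

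**Figure D2:**
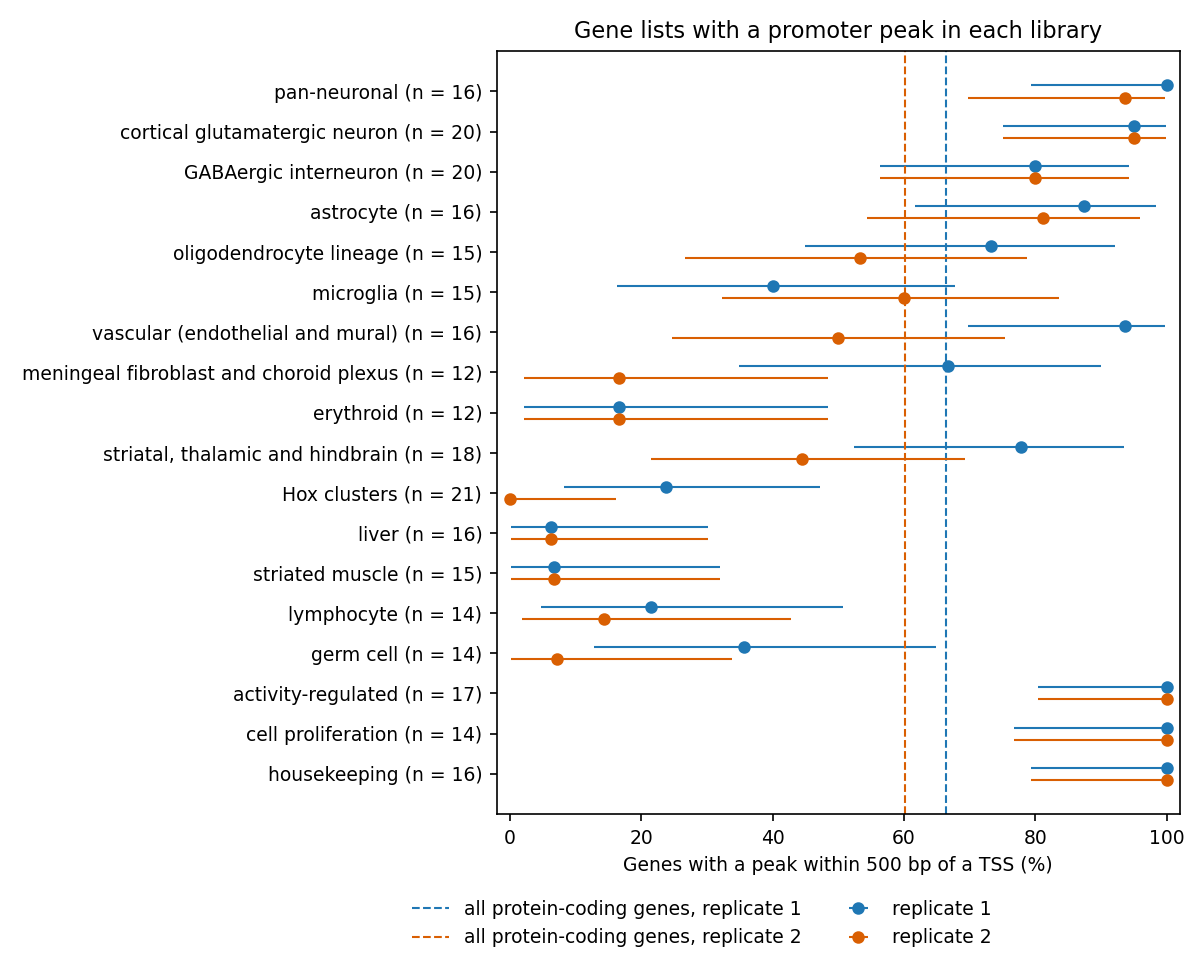
Share of the genes of each list with a peak within 500 bp of a TSS (horizontal axis, %) in replicate 1 and replicate 2. Points are shares, bars are exact 95% binomial intervals over the genes of the list, and dashed lines mark all protein-coding genes (66.4% in replicate 1 and 60.2% in replicate 2). The vascular list stands at 15 of 16 genes in replicate 1 and 8 of 16 in replicate 2.

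The 2 libraries were not alike in which cell types' promoters were open. Vascular genes had a TSS peak in 15 of 16 cases in replicate 1 and 8 of 16 in replicate 2, and meningeal and choroid plexus genes in 8 of 12 and 2 of 12. None of these genes had a peak in replicate 2 alone. That was rare over all protein-coding genes too, of which 14483 had a TSS peak in replicate 1, 13149 in replicate 2 and 12959 in both. In replicate 1 taken alone the vascular list was above other genes (Fisher's exact adjusted p = 0.0282), and the meningeal list was no longer below them (adjusted p = 1). With replicate 2 alone the adjusted p-values were 0.505 and 0.0074. Hox genes had a TSS peak in 5 of 21 cases in replicate 1 and 0 in replicate 2, germ cell genes in 5 of 14 and 1 of 14, striatal, thalamic and hindbrain genes in 14 of 18 and 8 of 18, and oligodendrocyte lineage genes in 11 of 15 and 8 of 15. Microglial genes had a TSS peak in 6 of 15 cases in replicate 1 and 9 of 15 in replicate 2, but in equal numbers of peaks 6 of them ranked higher in replicate 1 and 3 in replicate 2. These counts set 1 library against 1, so the differences have no replicate check and no test.

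Named after their values were seen, the endothelial genes Cldn5, a tight junction protein of the blood-brain barrier (signal 4.38), Sox17 (4.28) and Flt1 (3.60) and the fibroblast collagen genes Col1a1 (2.30) and Col1a2 (1.89) had a TSS peak in replicate 1 and none in replicate 2. In the longer list of replicate 2, Sox17 and Flt1 had a TSS peak and Cldn5, Col1a1 and Col1a2 had none. Slc2a1, the glucose transporter of the blood-brain barrier, had one in both (9.93 in replicate 1 and 4.14 in replicate 2), as did Slco1c1 (3.15 and 0.787), Foxc1, a factor of the meninges (5.63 and 0.842), and Pdgfra (2.84 and 1.71). Tek, Dcn and Folr1 had none in either. The microglial genes Cx3cr1 (0.712), C1qa (0.842) and C1qb (1.2), also named after their values were seen, had a TSS peak in replicate 2 and none in replicate 1. In the longer list of replicate 1, Cx3cr1 and C1qb had one and C1qa had none.

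**Figure D3:**
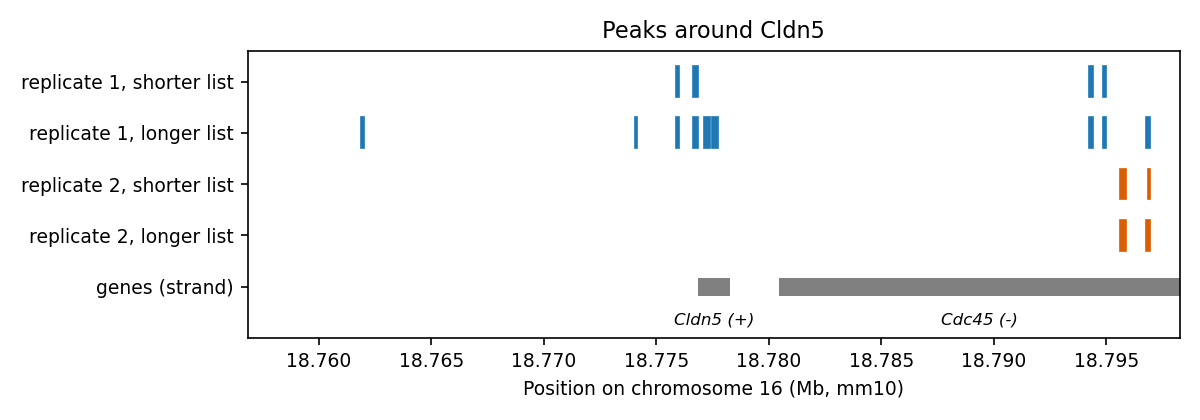
Peaks of both libraries around Cldn5 on chromosome 16 (18756847 to 18798262, horizontal axis in Mb, mm10), with the shorter and the longer peak list of each library and the annotated genes. Cldn5 lies at 18776847 to 18778262 on the plus strand, and the peak at its TSS (18776641 to 18776840) is present in replicate 1 and absent from both lists of replicate 2.

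Distal elements clustered around activity-regulated genes. These 17 genes had on average 2.76 shared peaks lying more than 1 kb from any TSS within the gene body and 10 kb on either side, against 0.738 in random lists matched on window length (ratio 3.74, two-sided permutation adjusted p = 0.0036 over 18 lists, the smallest value 10000 random lists can give). Counting all peaks of a single library in place of shared ones, the list was called in replicate 2 only. In replicate 1 alone the ratio was 2.41 (permutation adjusted p = 0.149), in replicate 2 alone 3.24 (0.0288), and with peaks more than 5 kb from any TSS it was 1.77 and not called. For the other 17 lists the adjusted p was 0.11 or higher. The ratios were 2.39 for the oligodendrocyte lineage (permutation adjusted p = 0.11), 1.89 for glutamatergic neurons (0.146), 1.87 for astrocytes (0.251) and 1.88 for lymphocyte genes (0.253). They were 0.342 for germ cell, 0.579 for liver, 0.67 for muscle and 0.514 for erythroid genes. The remaining ratios were 1.22 for pan-neuronal, 1.17 for interneuron, 1.44 for microglial, 1.12 for vascular, 0.878 for meningeal, 1.01 for striatal, thalamic and hindbrain, 0.962 for Hox, 1.62 for proliferation and 1.37 for housekeeping genes.

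The genes with the most shared distal peaks were mainly long ones. Gm20388 had 165, in a gene model whose window spanned 4455 kb and so covers many other genes. Fgfr2, a fibroblast growth factor receptor, had 63, also in a very wide gene model with a window of 2981 kb. These 63 peaks therefore need not belong to Fgfr2 itself. Gse1 had 33, Nfic, a nuclear factor I gene, 30, Auts2 and Nav2 27 each, Asic2 26, and Mid1, Prn and Ptprn2 25 each. Among these 10 genes the densest per unit of length were Prn, with 37.8 shared distal peaks per 100 kb, and Nfic (chromosome 10, 81396186 to 81455635), with 37.8 per 100 kb. Of 21911 protein-coding genes, 11223 had 0 shared distal peaks.

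Chromosome X carried fewer accessible sites than any autosome. It had 14.3 peaks per Mb in replicate 1 and 13 in replicate 2, against autosomal medians of 47.6 and 36.8. The autosomes ranged from 29.97 and 28.1 peaks per Mb on chromosome 3 to 71.7 and 50.7 on chromosome 11. The density on X was 0.30 times the autosomal median in replicate 1 and 0.353 times in replicate 2. With only the higher-signal part of each list it was 0.214 and 0.223 times that median. Males carry 1 copy of X. Protein-coding genes on X had a TSS peak in 51.6% and 47.4% of cases against 67.3% and 61.1% of autosomal genes. Chromosome Y had 59 peaks in replicate 1 and 31 in replicate 2.

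Footprints recurred between the animals at more positions than placement inside the same peaks would give. Of the 283332 footprints lying wholly within a peak of replicate 1, 46.4% overlapped a footprint of replicate 2, against 34.5% on average for placements at random in the same peaks. For the 238627 such footprints of replicate 2 the shares were 55.1% and 39.7% (permutation p = 0.0099 in each library, the smallest value 100 placements can give). Within shared peaks 66.4% and 72.1% overlapped. Peaks with more signal held more footprints. In the lowest quartile by signal 57.2% of replicate 1 peaks and 72.4% of replicate 2 peaks held one, and in the highest quartile 99.6% in both.

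Some footprints present in both libraries at the most accessible sites held 1 of the 26 motifs. Of 52 footprints in the named shared peaks that overlapped in both libraries 12 did, and none of the 4 at Hjurp, 5 at Fzr1 and 7 at Bahcc1. Of these 12, 5 lay in the peak near Gm21887, where several footprints hold the same run of bases and are not separate sequences. No background share was computed for these 52. The following 2 were chosen after their sequences were seen. At Snrnp70 the footprint at chromosome 7, 45395780 to 45395811, extended by 5 bp on each side, read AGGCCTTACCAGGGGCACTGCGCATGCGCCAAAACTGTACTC and held the consensus of NRF1, a regulator of nuclear genes for mitochondria. Replicate 2 had a footprint at 45395780 to 45395812. At Mxd1 the footprint at chromosome 6, 86669508 to 86669533, at the same bases in both libraries, read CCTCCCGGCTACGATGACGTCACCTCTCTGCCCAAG with the extension and held the CREB/ATF site TGACGTCA. Both lay in TSS-proximal peaks.

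Sites of the architectural protein CTCF and of several other factors were concentrated in footprints. CTCF sites (CCASYAGRKGGC) were in 1.35% of replicate 1 and 1.38% of replicate 2 footprints, and in 0.00699% and 0.0107% of equally wide segments of the same peaks outside footprints, a ratio of 194 (95% interval 123 to 304) and 129 (86.9 to 191). The ratios were 18.6 and 12.2 for SP/KLF, 12.5 and 11.1 for NRF1, 16.04 and 18.5 for EGR, 9.75 and 18.7 for CREB/ATF, 2.67 and 2.64 for YY1, and 1.53 and 1.504 for ETS. Against dinucleotide shuffles of the footprints all 7 stayed higher, at other sizes. The ratios were then 85.5 and 104 for CTCF, 5.08 and 5.96 for SP/KLF, 7.96 and 10.3 for NRF1, 3 and 2.56 for EGR, 50.2 and 34.55 for CREB/ATF, and 7.41 and 7.57 for ETS. For YY1 they were 38.3 (95% interval 12.2 to 121) and 103 (14.4 to 738), on 3 and 1 shuffle counts. The full palindromes of RFX and NFI were in 130 and 175 footprints of replicate 1 and in 259 and 95 of replicate 2, and in 0 background segments, at least 43.3-fold and 58.3-fold higher in replicate 1 and at least 86.3-fold and 31.7-fold higher in replicate 2 against a floor of 3 counts per library. Against dinucleotide shuffles NFI was 29.2-fold (95% interval 12.9 to 65.8) and 11.9-fold (5.77 to 24.4) higher.

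The sizes of these ratios depended on how far footprints were extended. Without extension they were 881 and 370 for CTCF, 46.5 and 29.4 for SP/KLF, 24.8 and 21.8 for NRF1, 17.3 and 44.8 for CREB/ATF, and 30.5 and 57.75 for EGR. With 10 bp on each side they were 83.7 and 51.5 for CTCF, 9.08 and 6.40 for SP/KLF, 6.96 and 6.91 for NRF1, 5.975 and 9.26 for CREB/ATF, 7.86 and 9.34 for EGR, and 1.63 and 1.958 for YY1. RFX was then 22.8-fold (95% interval 10.1 to 51.7) higher in replicate 1 and 89.3-fold (28.6 to 279) in replicate 2. In distal peaks alone YY1 was not called, with 9 footprints against 3 background segments in replicate 1 and 3 against 2 in replicate 2.

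A neuronal E-box was also concentrated in footprints, and more so in replicate 2. The NEUROD-type E-box CAGATGG, bound by the basic helix-loop-helix factors of cortical neurons, was in 0.805% of footprints in replicate 1 and 2.27% in replicate 2, with ratios of 1.53 (95% interval 1.43 to 1.64) and 3.51 (3.31 to 3.71), and of 2.23 and 5.92 against dinucleotide shuffles. The difference between the libraries has no replicate check. Altogether 11 of 26 motifs were higher and 8 lower than in the same-peak background in both libraries (two-sided Fisher's exact tests per library, Benjamini-Hochberg adjusted over 26 motifs).

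The lower motifs included AP-1, POU octamer, both homeobox forms, TBR/T-box, GATA and PU.1, with mean ratios between 0.382 for GATA and 0.687 for AP-1. This direction depended on the background. Against dinucleotide shuffles of the footprints themselves AP-1 (1.37), POU octamer (1.94), homeobox (1.69), PU.1 (1.57) and LHX/DLX homeobox (1.11, not called) turned higher, and GATA was no longer called (0.838 in replicate 1, Fisher's exact adjusted p = 0.147, and 0.502 in replicate 2). TBR/T-box lost its call without extension of the footprints (0.723 in replicate 2, Fisher's exact adjusted p = 0.225) and in distal peaks alone (0.784, 0.163). Footprints had a GC content of 62.7% in replicate 1 and 59.98% in replicate 2, against 57.1% and 53.5% in the same-peak background. MEF2, the SOX pair, the SOX single site, the REST left part, HNF4A and MYOD were not called in the same direction in both libraries, and HNF1 was found in 0 footprints. The REST part had a ratio of 2.36 in replicate 1 and 0.814 in replicate 2, and the MYOD form CAGCTGTT 0.631 and 1.49.

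**Figure D4:**
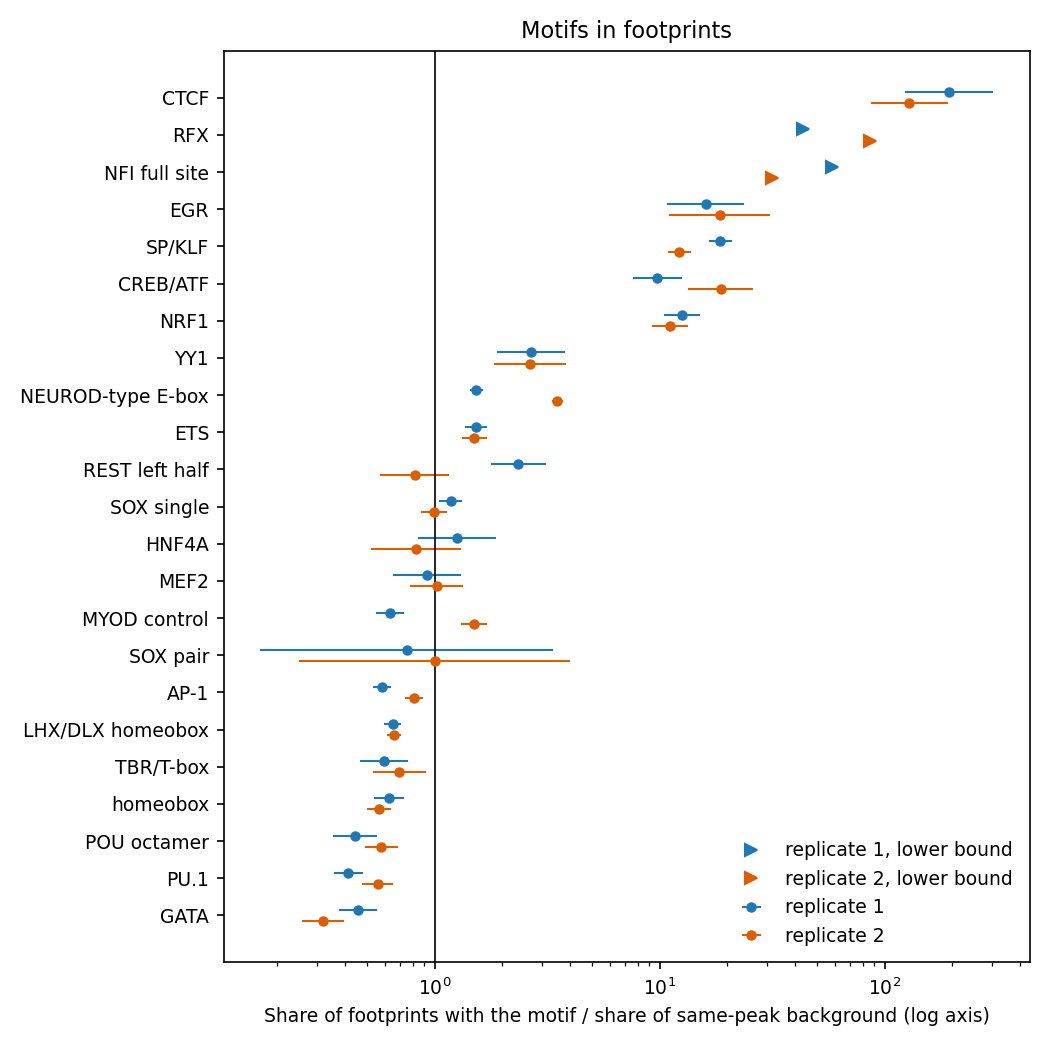
Ratio of the share of footprints holding each motif shown to the share of equally wide same-peak background segments (horizontal log axis) in replicate 1 and replicate 2, with 95% intervals from counting error. Triangles are lower bounds against 0 background counts. CTCF stands at 194 and 129, and the NEUROD-type E-box at 1.53 and 3.51.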

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

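The longer peak list, TSS-proximal pairs and every footprint were alternatives chosen after seeing the data. Peak overlap stayed far above placements in all settings run, between 34.98% and 58.4% of replicate 1 and between 51.1% and 70.8% of replicate 2 peaks. The odds ratio of promoter share and the X density also kept their direction, and the odds ratio its side of the threshold. The number of called motifs stayed similar, but the direction of several turned round against dinucleotide shuffles, as given below. Of the main results, 50 comparisons with an alternative kept their call or stayed within their error, 10 moved further, 2 gave fewer and 1 gave more called lists, and of single lists and motifs 421 did, while 10 gained a call, 14 lost one and 10 turned round.

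The Spearman correlation of signal, 0.724, moved to 0.745 with 50% reciprocal overlap, 0.72 with the higher-signal part, 0.561 for distal and 0.897 for TSS-proximal pairs. Support of library-only peaks fell at an FDR of 0.01 to 18.9% in replicate 1 and 28.3% in replicate 2, and with 50% of the peak covered to 22.5% and 34.9%, as both settings ask for more of the same bases. Over every footprint, inside a peak or not, 36.5% of replicate 1 and 46.7% of replicate 2 footprints were shared. The number of lists called for distal peaks, 1, was 2 with a margin of 50 kb, where the oligodendrocyte lineage joined, and 0 with peaks more than 5 kb from a TSS. It ranged from 0 to 1 with each replicate alone, and the cause was not tested.

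The difference from other genes in percentage points was -9.38 for the vascular and -42.7 for the meningeal list. With each replicate left out in turn it ranged from -10.3 to 27.4 and from -43.6 to 0.31, the higher value in both without replicate 2. The number of TSS lists called was 12 with either replicate alone and 8 with CpG matching. Against dinucleotide shuffles the mean ratio turned round for AP-1 (1.37), MEF2 (6.20), the POU octamer (1.94), homeobox (1.69), LHX/DLX homeobox (1.11), PU.1 (1.57) and MYOD (1.59). The called motifs then split into 17 higher and 2 lower, against 11 and 8 with the same-peak background. The mean ratio of MYOD was 1.49 without replicate 1 and 0.631 without replicate 2. The cause was not tested.

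Support at an FDR of 0.1 gave no value, because the listed runs end at 0.05, and a stricter footprint threshold gave none, because the score is constant. No paired analysis was possible because there is a single group. If 1 step of the signal is 1 counted cut, peaks of 1 library alone rested on a median of 142 cuts in replicate 1 and 132 in replicate 2, against 403 and 267 for shared peaks, so their signal has the larger relative counting error.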

Other observations

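The comparison of library-only peaks by motif, the percentiles of gene lists, and the tests of depth, threshold, promoter GC content, neuronal share, GC content in replicate 1 and cell mix were chosen after the results they measure were seen. Distal peaks found in replicate 2 alone carried several motifs at other rates than those found in replicate 1 alone. Within deciles of GC content the odds ratio of replicate 2 against replicate 1 was 18.7 for RFX (95% interval 7.92 to 44.1), 2.48 for MEF2 (1.97 to 3.11), 2.24 for the POU octamer (1.93 to 2.60) and 1.36 for homeobox sites (1.24 to 1.481). CTCF (0.183, 0.158 to 0.212), full NFI sites (0.183, 0.104 to 0.322), SP/KLF (0.397, 0.331 to 0.476), single SOX sites (0.702, 0.636 to 0.774) and PU.1 (0.729, 0.651 to 0.816) leaned to replicate 1. The intervals treat peaks as independent and describe these 2 libraries.

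In equal numbers of peaks, the glutamatergic promoters stood at a median percentile of 73.8 in replicate 1 and 85.4 in replicate 2. Their median difference, -10.1 percentile points, lay below the matched range of -0.749 to 10.3. Pan-neuronal promoters stood at 80.6 and 86.3, with a median difference of -7.65 against a matched range of -1.52 to 7.91. Named after their values were seen, Neurod6 (44.4 and 89.1), Tbr1 (32.4 and 80.7), Bcl11b (27.5 and 85.7) and Neurod2 (75.4 and 94.5) ranked lower in replicate 1, while Slc17a7 (54.7 and 0) ranked higher. Slc17a6 (61.1 and 33.3), a member of the striatal, thalamic and hindbrain list, also ranked higher. Of the 20 glutamatergic genes 14 ranked lower in replicate 1 and 6 higher. Interneuron promoters, with -1.18, lay below their matched range of 2.32 to 36.1, and activity-regulated promoters, with -1.26, below their range only with GC matched too (-0.906 to 2.55). The shift was not confined to neuronal lists. Astrocyte promoters, with -1.55, lay below their matched range of -0.923 to 12.5, but inside it with GC matched too (-2.06 to 7.60). Housekeeping and proliferation promoters differed by -0.534 and 0.41, within their matched ranges.

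Vascular and meningeal promoters had a peak in replicate 1 and none in replicate 2 for 13 of 28 genes, and the reverse for 0. Over all genes, too, a TSS peak in replicate 2 alone was far rarer than in replicate 1 alone. Depth or threshold stays open. Of the 23 genes with a peak in replicate 1, 43.5% lacked one in the longer list of replicate 2. In lists matched on replicate 1 signal the share was 10.7% (100th percentile). This percentile cannot decide the question, because the 2 lists were merged after their missing replicate 2 peaks were seen. Of the 13 genes, 76.9% lacked a peak in the longer list, against 53.2% of all genes with a peak in replicate 1 alone, not matched on signal. In replicate 2, 5 of the 13 had a base at an FDR of 0.05 or below. The median difference of the vascular genes, 55.8 percentile points, lay at the 99.78th percentile of lists matched on GC and level. This argues against GC content at the 5' end of the gene as the whole cause. GC content around other TSSs of a gene was not matched, and the vascular list was picked after the list counts were seen. For the meningeal genes GC content stays open, as their 44.9 points lay at the 97.14th percentile, inside their matched range of 1.26 to 45.5. A lower neuronal share alone, which would raise all non-neuronal promoters alike, stays open, because the range of standardised median differences over the astrocyte, oligodendrocyte, microglial, vascular and meningeal lists lay at the 96.59th percentile of 5 lists matched on level (97.48th with GC), while the 3 glial lists lay at the 0.98th, 22.6th and 22.2th percentiles. A candidate explanation is a larger share of vascular and meningeal cells in the tissue piece behind replicate 1, which stays open too, because distal peaks of replicate 1 alone were 1.24 times as frequent around these genes as around matched ones, which a two-sided permutation test with p = 0.481 could not tell from chance.

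A large part of each library's peaks had no partner in the other. The threshold may account for part of them, since 31.1% of the peaks of replicate 1 alone and 45.7% of those of replicate 2 alone overlapped the other library at an FDR of 0.05 or below. For the rest threshold and depth stay open, because the listed runs end at 0.05 and a weaker site counts as absent. GC content may account for part of the loss in replicate 2, where the shared share reached 95% in the highest decile, but is not the whole cause in replicate 1, where it lay between 41.5% and 71.2% over the deciles, and between 37.2% and 49.1% among distal peaks. A different mix of cell types stays open. The NEUROD-type E-box was more frequent in distal peaks of replicate 2 alone at equal GC content (odds ratio 3.11, 95% interval 2.95 to 3.28). Its excess in footprints of replicate 2 had been seen before. RFX, MEF2, the POU octamer and homeobox sites also leaned to replicate 2. CTCF (0.183, 0.158 to 0.212) and SP/KLF (0.397, 0.331 to 0.476) were among those that leaned to replicate 1. These odds ratios do not tell a different cell mix from a technical difference between the libraries. A GC bias of library preparation and a difference in cell mix are not exclusive, and differences between the 2 animals or dissections were not tested.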
